A study of Mus musculus with 36 samples.

How the data were processed

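C2C12 is a mouse myoblast line whose cells leave the cell cycle, fuse into multinucleated myotubes and switch on muscle genes when serum is reduced. Per the labels, myoblasts growing in DMEM with 20% fetal bovine serum were moved to DMEM with 2% horse serum, a serum poor in growth signals that is widely used to start this process. Separate plates were harvested at 12 times between 0 and 144 h, the 0 h plates still being in growth medium. Each time was harvested 3 times, from growths of successive passages, and the replicate numbers 1 to 3 of the labels are read here as those passages. The p-values therefore rest on 3 cultures of 1 cell line grown at successive passages. Total RNA was extracted with Trizol, amplified and labelled with biotin, and hybridised in 1 colour to Illumina Mouse WG-6 bead arrays, 1 array per culture. The 36 arrays lay on 6 chips of 6 arrays, and each chip held arrays of 1 replicate number only. The chips of replicate 1 held 0 to 6 h and 9 to 144 h. One chip of replicate 2 held 0, 1, 1.5, 48, 96 and 144 h, and the other held 2 to 24 h. One chip of replicate 3 held 0, 1, 1.5, 9, 12 and 24 h, and the other held 2, 3, 6, 48, 96 and 144 h.

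The authors deposited a raw table with the intensity of 46019 probes on each of the 36 arrays, on a linear scale from 91.5 to 72391, and this table was the starting point here. How the scanner software made these intensities is not given in the sources used here, and detection p-values and control beads were not used here. The authors also deposited a normalized table, whose values behave as log2 values because they rose by 1.05 per doubling of the raw intensity between 2000 and 40000. Within each array its order of probes was that of the raw table (lowest rank correlation 1), its column medians were 8.37 to 8.38, its lowest value was 8.33 and its highest 16.2. The method of that normalization and any offset in it are not given in the sources used here. The 44505 probes of the series matrix held the same values as the authors' normalized table. Both were used as alternatives. The arrays held 0 columns of other samples.

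Raw intensities were background corrected with the normexp method (offset 50), quantile normalized between arrays and put on the log2 scale in limma 3.58.1 under R 4.3.3. A log2 unit is a doubling of this background-corrected signal, and because of the offset the changes of dim genes are understated. Probes were kept when they lay above the median of all values, log2 7.09, on at least 3 arrays, which left 29812 probes. Gene names came from the platform annotation, updated through a table of RefSeq genes of the assembly GRCm38.p6. That gave 28471 probes with 1 symbol, 10 with several and 17538 that are unnamed here. Of the named probes, 28420 were matched by Entrez ID, 12 by accession and 39 kept the platform symbol, and 11 symbols were updated. No coordinates are printed because the build of the array design is not given in the sources used here. Of the kept probes 20162 had a name, and 9644 without one were tested apart. Where a gene had more than 1 kept probe, which held for 4792 genes, the probe with the highest mean signal stood for it, and 13251 genes were tested. Other probes of named genes are compared in the closing part. Prolactin-2c genes (Prl2c2, Prl2c3 and Prl2c4) are near-identical copies whose probes may read each other, so their values are uncertain as to the member.

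One limma model held all 36 arrays as 12 groups of 3, so that all groups shared 1 estimate of spread per gene (24 residual degrees of freedom, 28.6 with the prior). Each time was tested against 0 h, and 24 h was tested against 3 h and 144 h against 24 h, with Benjamini-Hochberg (BH) adjustment over the genes of each comparison, which limits the share of false calls. An adjusted p under 0.05 was a call. An F-test over the 11 changes against 0 h asked which genes differed among the times. All tests were two-sided. Changes are log2 differences with their standard error (SE), and levels are mean ± SD over 3 arrays. Gene lists were tested with camera, a limma test of whether the genes of a list shift more than the other genes do, at a preset correlation of 0.01 between genes and with BH adjustment over the lists. Calls were recomputed with the correlation estimated from the data. Of 33 lists fixed, 32 had at least 5 measured members and were tested. The list of leukocyte and macrophage markers had 4 measured members and was not tested. In the comparisons for which lists were tested, list counts are given over all genes tested, and where no second count stands beside them the count adjusted over the list alone was the same. The main comparisons, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from the additions named here.

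The genes named in the main comparisons of 3, 24 and 144 h with 0 h were the 6 largest rises and the 6 largest falls among called genes whose 3 differences between arrays of the same replicate number shared the sign of the change, leaving out predicted and RIKEN symbols. From each list that passed camera the 2 called members with the largest change were named, or the largest of each sign where both occurred. For 24 h against 3 h and 144 h against 24 h the 3 largest rises and falls were named. In addition 31 genes were named by symbol whatever their values. Of those, Myh3, Mki67, Ccnb1 and H19 had no named probe here, Mstn lay below the filter level, and 1 is not reported here. All other genes named were chosen after their values were seen, among them members of lists that did not pass and genes of the other times. The test of the lists at 24 h against 3 h was also added after the values were seen.

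Probes at or above a raw signal of 65000 were treated as saturated, a limit chosen after the data were seen. They made up 0.285% of raw signals and had log2 values of 15.6 or more. A gene saturated on every array of a group, or at or below the filter level on every array of a group, has only a bound there. Its change is given as "at least N-fold", from the brighter group's mean and, per array, the higher of the filter level and the dim probe's own signal, or is left out. Where only the mean of a group lay below the filter level, the gene is called dim there and its change is left out. Other probes are given with their changes even where they were dim. Actb and Gapdh, used widely as reference genes, were saturated at all times and have no fold.

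Whether the replicate numbers pair the arrays was checked before calls were compared. Arrays of the same number at different times, as deviations from their group means, had a median correlation of 0.376 over 198 pairs (lowest −0.268, highest 0.727, 175 pairs above 0.1), and arrays of different numbers had a median of −0.185 over 396 pairs. Of the 36 arrays, 33 correlated best with an array of their own number. The pairing was taken from the labels, which tie the harvests to successive passages, and the fit with the replicate number as a block is given beside a result where it changes the call or moves a count by over 1.5 times. Since each chip held 1 replicate number, the chip as a block also covers the passage. Its value is given beside counts and list shifts, with list medians within single chips that held both times. For counts, genes called without a passage were compared in sign with the chip of that passage that held both times, a check added after the data were seen. Fitted as a random block, the chip had a correlation of 0.274.

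Alternatives tried were the authors' normalized table, the series matrix, no background correction, scaling to the median, cyclic loess, no filter, a filter at the 75th percentile, every probe on its own, the replicate number as a block, the chip as a fixed and as a random block, only the arrays of the groups compared, an intensity trend with a robust prior, an estimated correlation for lists, and leaving out each replicate number or each array in turn. Single arrays were left out only for the gene counts of the comparisons. The replicate block with an estimated correlation was added after the data were seen. The steps were tested on simulated data shaped on 24 h against 0 h with 13251 genes. With 50 genes changed at each size, 30%, 92%, 100% and 100% were recovered at log2 changes of 0.5, 1, 2 and 3, and 6 of 167 calls were false. The simulated noise was independent between arrays and held no passage or chip effect, so these rates do not cover such effects. The number of arrays limits the precision, and the median SE of a change was 0.15.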

Results

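Gene expression was followed in C2C12 mouse myoblasts from growth medium through 144 h in 2% horse serum. The arrays formed 12 groups of 3 cultures from successive passages, harvested at 0, 1, 1.5, 2, 3, 6, 9, 12, 24, 48, 96 and 144 h. The median raw signal per array lay between 179 and 307 with a median of 217, and 106 to 194 probes per array were saturated. Correlations between arrays lay between 0.950 and 0.993, and 0 pairs held identical values. The number of arrays limits the precision. All levels are log2 signals as mean ± SD (n = 3), changes are log2 differences with their SE, and adjusted p-values come from limma, or from camera for gene lists. Genes outside the naming rule, among them all members of lists that did not pass, were chosen after their values were seen.

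The first question was how far expression differed among the 12 times. Levels of 5495 of the 13251 genes tested (41.5%) differed among the times by the F-test, against 3175 without passage 2 and 3429 without passage 3. Of these genes, 2094 had group means that spanned at least 1 log2 unit. Their highest mean fell at 0 to 1.5 h for 583 genes, at 2 to 12 h for 514, at 24 to 48 h for 248 and at 96 to 144 h for 749. The first principal component held 53.6% of the variance and followed time. The second held 12.5%, and passage accounted for most of it (r squared 0.702).

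**Figure D1:**
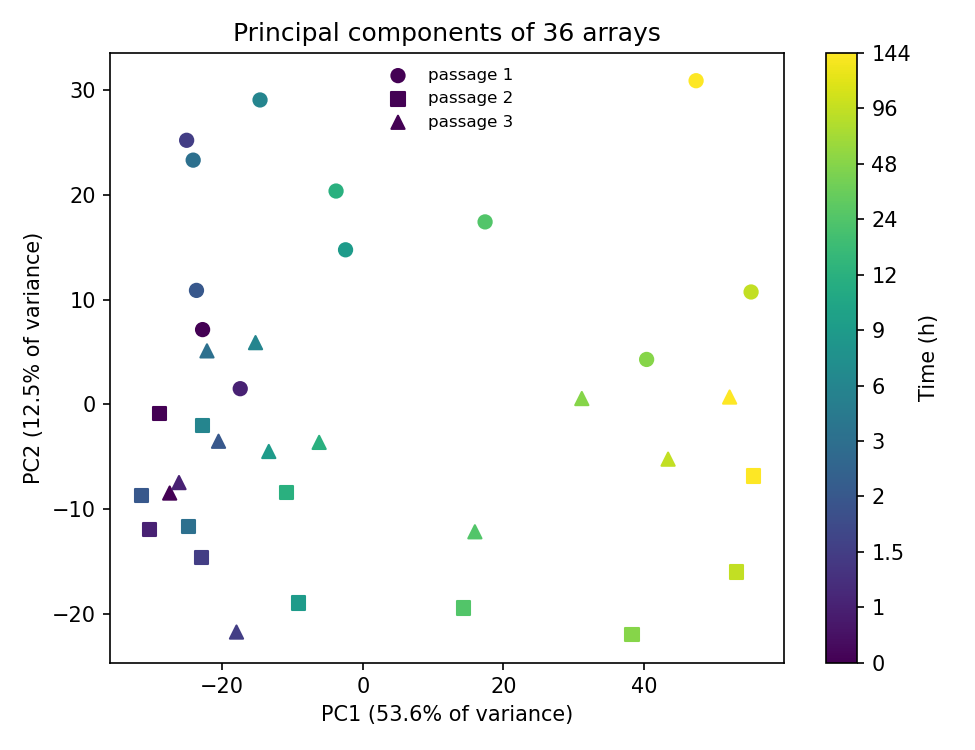
Each point is 1 of 36 arrays placed by its first (horizontal) and second (vertical) principal component score, with colour giving the time in h and shape the passage. The first component held 53.6% of the variance and ran with time, and the passages lay apart along the second, which held 12.5%.

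Among the muscle transcription factors, Myog (myogenin, needed for terminal differentiation) stood at 9.35 ± 0.77 at 0 h and 12.27 ± 0.01 at 24 h, and its rise first passed the test at 9 h (1.68, adjusted p = 0.022). Mef2c, a cofactor of the myogenic factors, first rose at 12 h (0.77, adjusted p = 0.0419) and reached 12.07 ± 0.57 at 144 h from 7.16 ± 0.11. Myf6 (MRF4), a late member of the family, passed from 96 h (1.69) and stood at 10.02 ± 0.45 at 144 h. Myod1, the factor that commits cells to muscle, differed from 0 h by −0.28 at 3 h, −0.09 at 24 h and 0.18 at 144 h and passed at none of these (adjusted p = 0.86, 0.905 and 0.711). Myf5 stood at 7.98 at 3 h and 7.48 at 144 h and did not pass either. The fusogen gene Mymk (myomaker) and the creatine kinase gene Ckm first rose at 9 h, by 2.10 (adjusted p = 0.0068) and 1.98 (adjusted p = 0.0023). Cdkn1a (p21), an inhibitor of cyclin-dependent kinases, first rose at 6 h (0.88, adjusted p = 0.0169), and its relative Cdkn1c (p57) at 9 h (1.75, adjusted p = 2.17e-05), with its highest mean of 14.71 at 24 h. With the passage as a block Cdkn1a already passed at 3 h. First times in this paragraph are first calls in the fit without a block and not times of onset. Id1, which blocks myogenic factors by binding their partners, was lower from 1 h (−0.89, adjusted p = 0.0162), and Id3 from 1.5 h (−1.04, adjusted p = 0.0114). The growth-response gene Fos passed at 1 h alone among the times tested (1.48, adjusted p = 0.0162), and Myc rose by 0.70 at 1 h (adjusted p = 0.0381).

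**Figure D2:**
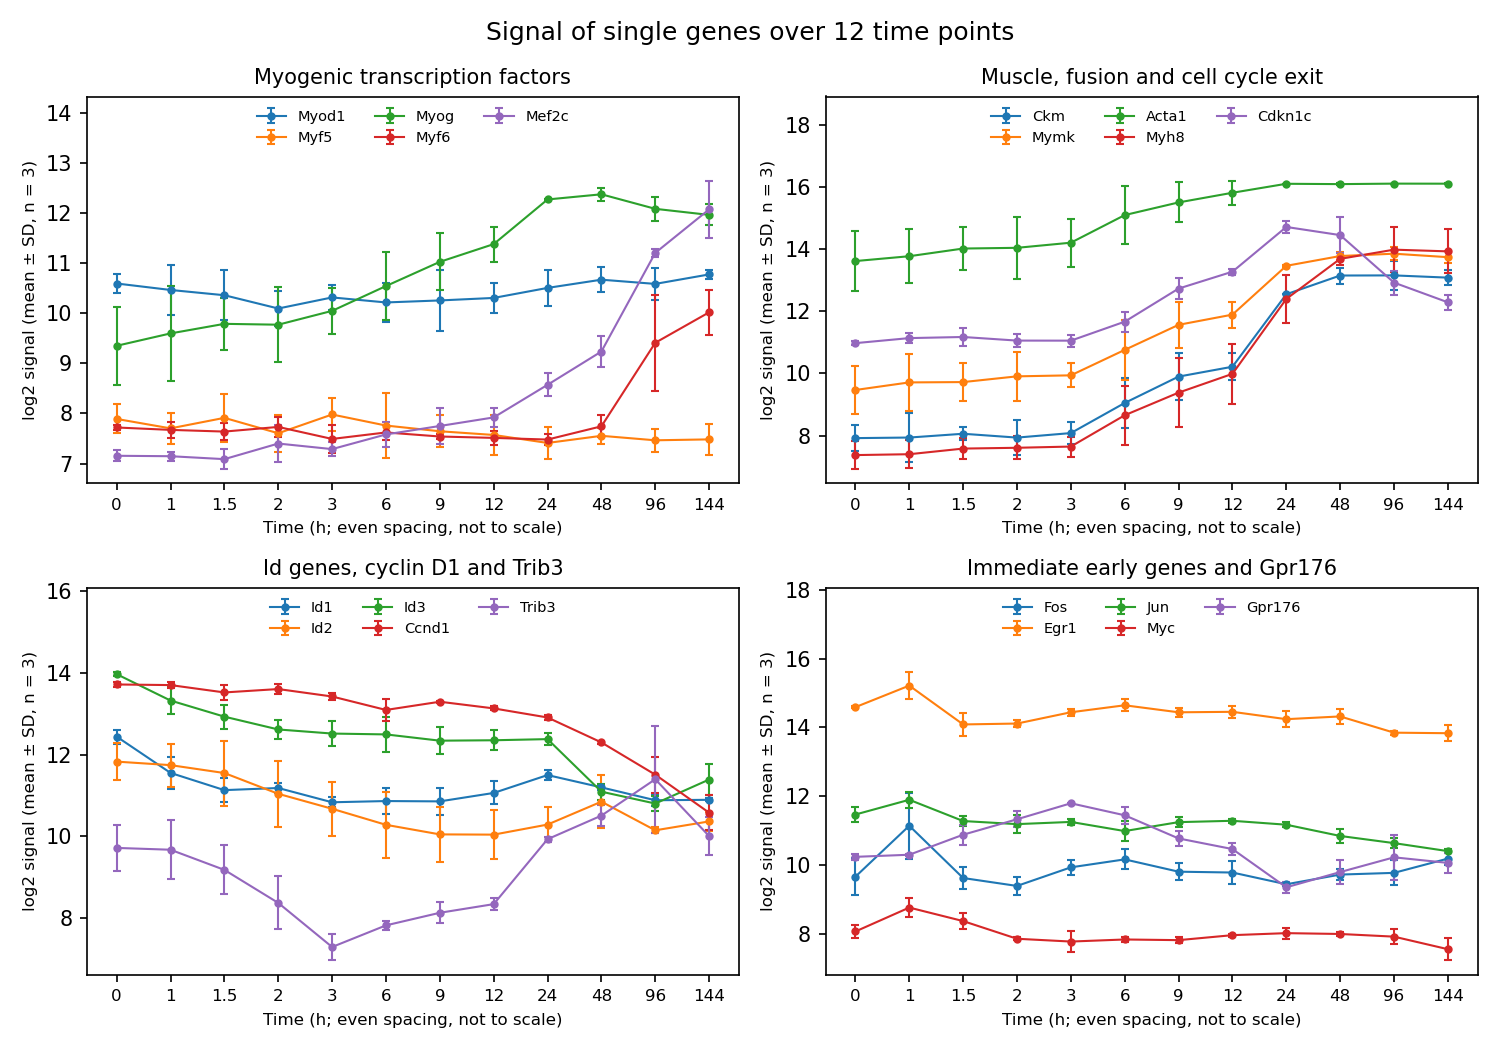
Mean log2 signal with SD bars (n = 3, vertical) at each of the 12 times in h (horizontal, evenly spaced and not to scale) for 20 genes in 4 panels. Myog rose from 9.35 at 0 h to 12.27 at 24 h, Mef2c reached 12.07 at 144 h, and Trib3 fell from 9.72 at 0 h to 7.30 at 3 h.

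The count of genes past the test against 0 h did not grow at every step, with 153 at 2 h but 135 at 3 h, and 4280 at 96 h but 4126 at 144 h. From 2 to 3 h it grew with the passage as a block (401 to 524) and with the chip as a fixed block (372 to 582). From 96 to 144 h it fell with both blocks (5333 to 5025, and 5210 to 4850). At 1 h, 45 genes passed (30 higher, 15 lower), at 1.5 h 95 (46 and 49), at 2 h 153 (73 and 80), at 6 h 207 (86 and 121), at 9 h 347 (207 and 140) and at 12 h 476 (292 and 184). At 48 h, 3743 genes passed (1763 higher, 1980 lower), and at 96 h 4280 (1993 and 2287). With the passage as a block the counts at 1, 1.5, 2, 6, 9 and 12 h were 76, 255, 401, 673, 828 and 1060. The chip as a fixed block gave 97, 283, 372, 725, 858 and 1029 at these times, and 4611 at 48 h and 5210 at 96 h. The chip of a passage that held both times was compared with the genes called without that passage. Signs matched for 33 of 33 genes at 1 h and 87 of 93 at 1.5 h on the chip of passage 1, for all 69 at 2 h and all 75 at 6 h there, and for all 73 at 9 h and all 115 at 12 h on the chip of passage 3. On the chip of passage 2 they matched for 97.8% at 48 h and 98.9% at 96 h. Without passage 2 the counts at 1, 1.5, 2, 6, 9 and 12 h were 5, 10, 9, 32, 110 and 168, and without passage 3 they were 4, 0, 0, 16, 73 and 115. The counts of 0 in limma stood beside 511 genes at 1.5 h and 637 at 2 h with an unadjusted p under 0.05. A share of 0.05 of the 13251 genes tested is expected there without any change, and neither number exceeded it. Without passage 1 there were 69 at 2 h, 75 at 6 h and 185 at 9 h, and without passage 2 there were 2231 at 48 h and 2702 at 96 h. Without single arrays the lowest counts at 1, 1.5, 2, 6, 9 and 12 h were 19, 40, 62, 60, 143 and 241. Scaling to the median changed the split to 12 higher and 16 lower at 1 h, 11 and 22 at 1.5 h, 40 and 23 at 6 h, and 1212 and 2699 at 96 h. At 12 h the majority turned to lower genes with the passage as a block (494 higher, 566 lower), with the chip as a fixed block (469 and 560) and as a random block (451 and 458), and at 96 h to higher genes with cyclic loess (2234 and 2083). At 1.5, 2 and 6 h it turned when some passages or arrays were left out, and at 1.5 and 2 h with every probe on its own.

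**Figure D3:**
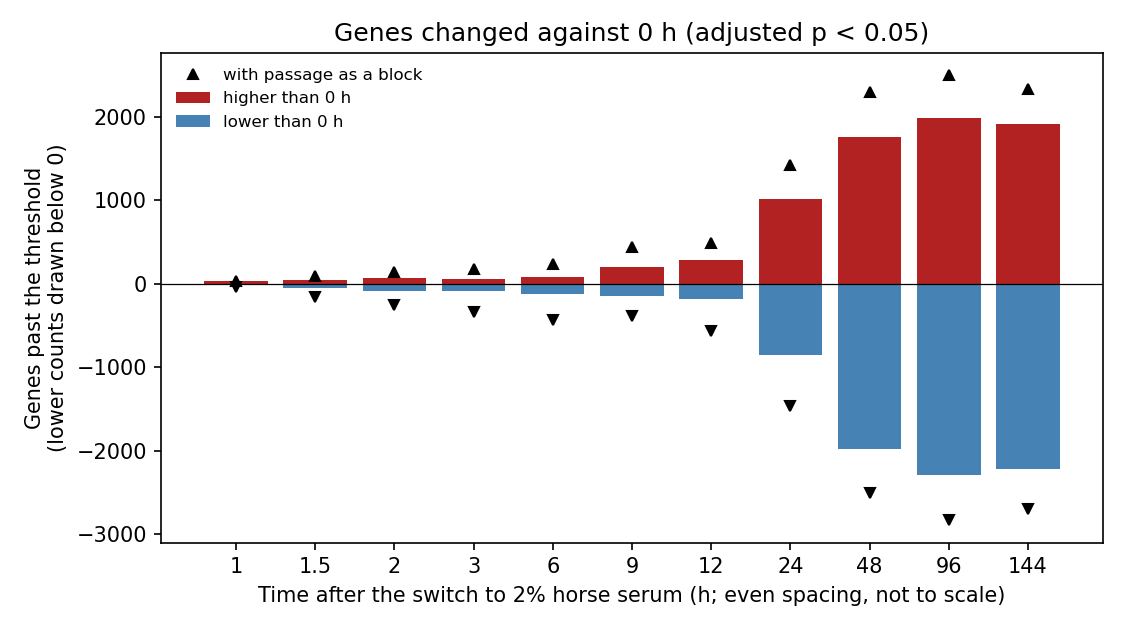
Bars give the number of genes past the threshold against 0 h (vertical, lower genes drawn below 0) at each time in h (horizontal, evenly spaced), and triangles give the counts with passage as a block. The count of higher genes was 30 at 1 h, 1014 at 24 h and 1912 at 144 h.

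The comparison of 3 h with 0 h asked what changed early after the switch to low serum. Transcripts of the stress-response genes Trib3, a pseudokinase, and Chac1, an enzyme that degrades glutathione, fell by 2.42 (SE 0.426, adjusted p = 0.0022) and by 1.90 (SE 0.31, adjusted p = 0.0011). Trib3 stood at 7.30 ± 0.32 against 9.72 ± 0.57 at 0 h. Id1 was lower at 10.83 ± 0.13 against 12.44 ± 0.17 (−1.61, adjusted p = 7.56e-06) and Id3 at 12.51 ± 0.31 against 13.96 ± 0.05 (−1.45, adjusted p = 0.000377). Also lower were the chemokine gene Ccl7 (−1.03, adjusted p = 0.0383) and Cish, a suppressor of cytokine signalling (−0.90, adjusted p = 0.000377). Gpr176, an orphan G protein-coupled receptor, rose the most, from 10.24 ± 0.08 to 11.79 ± 0.01 (1.56, SE 0.216, adjusted p = 0.00023). It was followed by Stc2, a secreted glycoprotein (1.04, adjusted p = 0.000377), the metalloproteinase inhibitor Timp3 (0.93, adjusted p = 0.0487), the meiotic gene Rec114 (0.89, adjusted p = 0.0043), the actin-binding protein gene Aif1l (0.88, adjusted p = 2.04e-06) and the muscle kelch protein gene Klhl40 (0.88, adjusted p = 0.0144). Another Id1 probe differed by −0.76 (adjusted p = 0.00137), another Stc2 probe by 0.29 (adjusted p = 0.685), and others of Timp3 by 0.24 (adjusted p = 0.949) and 0.71 (adjusted p = 0.0287). Those of Trib3, dim at 3 h, differed by −0.45 (adjusted p = 0.812) and −0.86 (adjusted p = 0.353), so a fault of the Trib3 probe used stays open.

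Ribosome biogenesis genes, which make and assemble ribosomal subunits, lay higher as a list at 3 h. Their median was 0.31 over 30 members, 1 rose (Rrp12, 0.81, adjusted p = 0.00612) and 29 did not pass, while 6 rose when adjusted over the list alone. The list passed (adjusted p = 1.07e-10, and 3.38e-11 with the chip as a block, median 0.26 within a chip), but not with an estimated correlation between genes (adjusted p = 0.0765 with an estimated correlation). Cholesterol synthesis genes lay lower, with a median of −0.28 over 19 members (adjusted p = 0.00371, chip block 0.00159, median −0.26 within a chip, and 0.613 with an estimated correlation). In that list 0 members passed in limma, over all genes or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The first enzyme of that pathway measured here, Hmgcs1, differed by −0.45 (adjusted p = 0.681). Circadian clock genes had a median of −0.16 over 14 members (adjusted p = 0.00183, chip block 0.00288, median −0.32 within a chip, and 0.096 with an estimated correlation), with a lower repressor Bhlhe40 (−0.62, adjusted p = 0.0225) over all genes and 3 lower when adjusted over the list alone. The list of Id genes and targets of BMP and TGF-beta signalling, 10 genes, had 2 lower members, Id1 and Id3, and 1 higher and 4 lower when adjusted over the list alone. Its median was −0.10 and its mean −0.41 (adjusted p = 0.0244, chip block 0.00288, median −0.11 within a chip, and 0.096 with an estimated correlation).

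The contractile genes were also higher as lists at 3 h without any member that passed in limma, over all genes or adjusted over the list alone. Sarcomere genes had a median of 0.27 over 33 members (adjusted p = 0.0072, chip block 7.77e-06, and 0.613 with an estimated correlation), with 1 higher at an unadjusted p under 0.05 and a median of 0.09 within a chip. Genes of the actin cytoskeleton that answer to serum response factor (SRF) had a median of 0.17 over 18 members (adjusted p = 0.0159, chip block 0.0149, median 0.15 within a chip, and 0.316 with an estimated correlation), with 5 higher at an unadjusted p under 0.05. The sarcomere call was also lost in the authors' normalized table (adjusted p = 0.059), in the series matrix (0.0587) and without passage 3 (0.154), and the SRF call with scaling to the median (0.105) and without passage 3 (0.108). Acta1, the skeletal actin gene, differed by 0.59 (adjusted p = 0.81), Myog by 0.70 (adjusted p = 0.637) and Cdkn1a by 0.52 (adjusted p = 0.275, or 0.0356 with the passage as a block). Id2 differed by −1.15 (adjusted p = 0.306, or 0.00114 with the block). The stress-response list (integrated stress response and unfolded protein response) had 3 lower members of 27, Trib3, Chac1 and Cebpb (−0.61), and did not pass (adjusted p = 0.259). Calcium handling genes did not pass (adjusted p = 0.0694, or 0.0389 with the passage and 0.00736 with the chip as a block), nor did mitosis genes (adjusted p = 0.0622, or 0.0242 with the chip as a block). With an estimated correlation both had adjusted p = 0.613, and 0.489 and 0.692 when the passage block was added. Reference genes, expected to be steady in many tissues, had 0 of 12 members past the test in limma over all genes, 1 up adjusted over the list alone, and a median of 0.00.

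At 3 h limma called 135 genes (55 higher, 80 lower), of which 2 rose and 5 fell at least 2-fold. With the passage as a block there were 524 and with the chip as a block 582. Leaving out passage 1, 2 or 3 left 29, 6 and 1, and all 29 had the same sign on the chip of passage 1, which held both times. Leaving out the 3 h array of passage 1 or 3 left 50 and 69, and leaving out the 0 h array of passage 1, 2 or 3 left 83, 60 and 75. Of the 14 named genes called, Aif1l kept its call in all 3 leave-outs of a passage. Where 6 lists passed with all arrays, 10 did without passage 1 and 2 without passage 3. The Id list lost its call without passage 2 or 3 (highest adjusted p = 0.274) and cholesterol synthesis without passage 3 (0.154). Scaling to the median gave 8 higher and 57 lower genes, and the calls of Bhlhe40 (adjusted p = 0.0825), Rec114 (0.0568) and Rrp12 (0.106) were lost there. In the authors' normalized table and in the series matrix Klhl40 (adjusted p = 0.28 in both) and Trib3 (−1.12 in both, adjusted p = 0.152 and 0.153) were not called. Timp3 lost its call in these (adjusted p = 0.0584 and 0.0586), with scaling to the median (0.3), cyclic loess (0.0577), no filter (0.0598) and the chip as a block (0.052).

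After 24 h, the second main time, the question was what changed when differentiation was under way. The muscle program was high. Perinatal myosin Myh8 stood at 12.40 ± 0.77 against 7.37 ± 0.45 (5.02, SE 0.509, adjusted p = 1.64e-08), and myosin-binding protein Mybph at 15.14 ± 0.15 against 10.14 ± 0.99 (5.01, adjusted p = 6.57e-08). The Z-disc protein gene Actn2 rose by 4.92 (SE 0.433, adjusted p = 1.06e-09), the sarcoplasmic calcium store gene Casq2 by 4.73 (adjusted p = 4.06e-08) and the embryonic myosin light chain gene Myl4 by 4.65 (adjusted p = 1.56e-09), although another Myl4 probe differed by 0.64. Ankrd2, an ankyrin-repeat protein of stretched muscle, was at least 21.9-fold higher (adjusted p = 3.86e-12) because it was dim at 0 h. Ckm reached 12.55 from 7.92 ± 0.42 (4.63, adjusted p = 2.61e-10) and Mymk 13.46 ± 0.03 from 9.47 ± 0.76 (3.99, adjusted p = 9.96e-08). The saturated Acta1 was at least 5.6-fold higher (adjusted p = 0.000601).

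Of 33 sarcomere genes 24 rose and 9 did not pass, with 28 up when adjusted over the list alone, and the median was 2.14 (adjusted p = 1.22e-30). Muscle energy metabolism had 12 of 17 members up (13 adjusted over the list alone) and a median of 1.24 (adjusted p = 9.46e-18), led by Ckm and the glycolytic Pgam2 (4.28). Calcium handling had 10 of 14 up (11 adjusted over the list alone) with a median of 1.37 (adjusted p = 2.34e-15), led by Casq2 and Hrc (3.71). Neuromuscular junction genes had 6 of 12 up (7 adjusted over the list alone) with a median of 0.46 (adjusted p = 5.84e-06), led by the acetylcholine receptor subunits Chrng (2.38) and Chrnd (1.60). Adhesion and fusion genes had 7 of 18 up (7 up and 2 down adjusted over the list alone) with a median of 0.17 and a mean of 0.65 (adjusted p = 5.03e-05), led by Mymk and by Cav3, a membrane protein of muscle that was at least 5.88-fold higher. Within a chip these 5 medians were 1.98, 1.31, 1.46, 0.43 and 0.26. With the chip as a block the adjusted p were 6.51e-37, 2.66e-17, 1.81e-14, 1.55e-05 and 8.72e-05, and with an estimated correlation all 5 calls held (adjusted p = 0.00356, 0.00356, 0.00123, 0.00546 and 0.00123).

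Growth-related groups moved in both directions at 24 h. Cdkn1c stood at 14.71 ± 0.20 against 10.97 ± 0.07 (3.74, SE 0.225, adjusted p = 1.04e-12), and Cdkn1a at 15.91 against 13.96 ± 0.44 (1.95, adjusted p = 1.43e-08). The cyclin gene Ccnd1 was lower (−0.81, adjusted p = 0.000891). The cell cycle exit list had 5 of 14 members up (Cdkn1c, Cdkn1a, Ccnd3, Gadd45b and Rb1) and Cdkn2d down (−0.58), with the same counts adjusted over the list alone. Its median was −0.07 while its mean was 0.45 and its test pointed up (adjusted p = 0.0394). That call did not hold with the passage as a block (adjusted p = 0.104) or the chip as a block (0.114, median −0.08 within a chip), nor with an estimated correlation (adjusted p = 0.0788 with an estimated correlation). Mitosis genes had 11 of 34 down, with examples Cenpe (−1.50) and Pttg1 (−1.12), 24 down when adjusted over the list alone and a median of −0.70 (adjusted p = 8.41e-09, chip block 7.74e-07, median −0.69 within a chip, and 0.146 with an estimated correlation). DNA replication genes had 2 of 29 down, Mcm4 (−0.63) and Tyms (−0.60), 1 down when adjusted over the list alone and a median of −0.33 (adjusted p = 0.000728, chip block 0.0237, median −0.37 within a chip, and 0.418 with an estimated correlation). Ribosome biogenesis had 16 of 30 up, among them Rrp12 (1.43) and Rrp9 (adjusted p = 1.49e-05), 18 adjusted over the list alone and a median of 0.45 (adjusted p = 2.98e-10, chip block 2.45e-09, median 0.43 within a chip), and held with an estimated correlation (adjusted p = 0.0166).

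Id genes and BMP and TGF-beta targets had 5 of 10 members down at 24 h, Id1 (−0.94), Id2 (−1.54), Id3 (−1.59), Ltbp2 (−0.94) and Grem1, and 5 adjusted over the list alone. The list median was −0.73 (adjusted p = 0.000289, chip block 8.05e-05, median −0.56 within a chip), and the call held with an estimated correlation (adjusted p = 0.00356). Immediate early genes had 6 of 30 down, the largest being Egr2 (−0.88), and Plk2 up (0.54), with the same counts adjusted over the list alone, a median of −0.16 (adjusted p = 0.0312, chip block 0.0682, median −0.09 within a chip) and adjusted p = 0.222 with an estimated correlation. SRF and actin genes had Flna (−0.63) and Tpm4 (−0.53) down of 18, also adjusted over the list alone, and a median of −0.24 (adjusted p = 0.0261, chip block 0.0386, median −0.18 within a chip, and 0.182 with an estimated correlation). Oxidative phosphorylation had 8 of 46 up, among them Cyc1 (0.65) and Uqcrq (0.66), 9 adjusted over the list alone, and a median of 0.18 (adjusted p = 0.000562, chip block 0.00105, median 0.18 within a chip, and 0.14 with an estimated correlation). Extracellular matrix genes split, with Dcn (0.90) and Col4a1 (0.64) up and Mmp14 (−0.49), Nid1 (−0.59) and Lox (−1.37) down of 27, the same adjusted over the list alone. Their median was −0.19 (adjusted p = 0.0394, chip block 0.0494, median −0.18 within a chip, and 0.287 with an estimated correlation).

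Heat shock genes had 3 of 10 members up at 24 h, Cryab (1.15), Hsph1 (1.01) and Hspb8 (0.64), also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0394, chip block 0.0265, median 0.06 within a chip, and 0.0791 with an estimated correlation). Neuronal markers had 3 of 9 down, Gap43 (−1.17), Stmn2 (−1.14) and Eno2 (−0.48), with 5 down adjusted over the list alone and a median of −0.48 (adjusted p = 0.0241, chip block 0.0129, median −0.40 within a chip). The neuronal list had adjusted p = 0.222 with an estimated correlation, or 0.0342 when the passage block was added. Imprinted genes had Cdkn1c and Mest (1.15), a growth-related hydrolase, up of 11, with 3 up and 1 down adjusted over the list alone and a median of 0.12 (adjusted p = 0.0395, or 0.0555 with the passage and 0.0386 with the chip as a block, median 0.15 within a chip, and 0.0791 with an estimated correlation). Notch pathway genes did not pass (median 0.25, adjusted p = 0.0612, or 0.0412 with the passage and 0.0386 with the chip as a block, and 0.101 with an estimated correlation or 0.0719 when the passage block was added to it), with 3 of 13 up, Heyl (1.56), Hey1 (0.60) and Nrarp (0.50), and 4 adjusted over the list alone. Over 13 other settings, calls at 24 h were lost in 8 for imprinted genes (highest adjusted p = 0.0708), in 7 each for cell cycle exit (0.114) and extracellular matrix (0.156), in 4 for immediate early genes (0.0682), in 3 for SRF and actin genes (0.113) and in 1 for heat shock genes (0.106). The authors' normalized table and the series matrix, which hold the same values, were both among them for imprinted, cell cycle exit and extracellular matrix genes. The remaining lists did not pass, among them the myogenic transcription factors (3 of 13 up, 1 down, adjusted p = 0.336). Markers of adipocytes (3 of 12 down), osteoblasts (2 of 8 down), chondrocytes (1 of 8 down) and reserve cells (3 up and 3 down of 13, or 4 and 3 adjusted over the list alone) had adjusted p of 0.167, 0.068, 0.834 and 0.462. Reference genes had 1 of 12 up, the transferrin receptor gene Tfrc (1.26), and a median of −0.13 (adjusted p = 0.495). Of the 4 leukocyte markers measured, Cd14 was lower (−0.70) and Adgre1, Lyz2 and Laptm5 did not pass.

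The largest falls at 24 h were in Hgf, which encodes hepatocyte growth factor (8.16 ± 0.16 against 10.59 ± 0.12, −2.43, adjusted p = 1.28e-09), the endopeptidase gene Phex (−2.28, adjusted p = 6.29e-07), Car3, a carbonic anhydrase (−2.20, adjusted p = 0.00128), and Ranbp3l (−2.16, adjusted p = 3.05e-08). The prolactin-family genes Prl2c4 (−2.23) and Prl2c3 (−2.19) were also lower, with the member uncertain. Igf2, a muscle growth factor, differed by 1.57 without passing (adjusted p = 0.0676, or 6.89e-05 with the passage as a block), as did Hes1 (0.53, adjusted p = 0.0728, block 0.00664) and Egr1 (−0.35, adjusted p = 0.186, block 0.0416). Mef2c rose by 1.42 (adjusted p = 1.62e-05) and Mef2a by 0.70 (adjusted p = 0.0155). The other probes of Mcm4, Uqcrq and Cenpe differed by 0.17, −0.02 and −0.16 and were dim at both times, as was 1 of the Mef2c probes (−0.06), while the other Mef2c probe differed by 0.25. Those of Stmn2, Id1 and Mest differed by −0.12, −0.56 and 0.64, the 3 others of Tyms by −0.49, −0.31 and 0.02, of Dcn by 0.84, 0.09 and 0.92, and of Tpm4 by −0.46, −0.61 and −0.03.

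In all 1860 genes changed at 24 h (1014 higher, 846 lower), 274 rising and 124 falling at least 2-fold, against 2890 with the passage and 2735 with the chip as a block. The majority turned to lower genes with the passage as a block (1430 higher, 1460 lower), with the chip as a fixed block (1326 and 1409) and as a random block (1351 and 1357), with scaling to the median (630 and 645) and with only the arrays of both times (821 and 887). There were 780 without passage 2, 868 without passage 3 and 1214 without the 0 h array of passage 2. Of the 868, 866 had the same sign on the chip of passage 3, which held both times. Of the 49 named genes called, 30 kept their call in all 3 leave-outs of a passage and 0 changed sign. For the largest rises and falls the sign could not change, since the naming rule asked for the same sign in every passage. Calls of Dcn, Flna, Mef2a, Plk2, Pttg1 and Tyms were lost under at least 1 other processing.

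**Figure D4:**
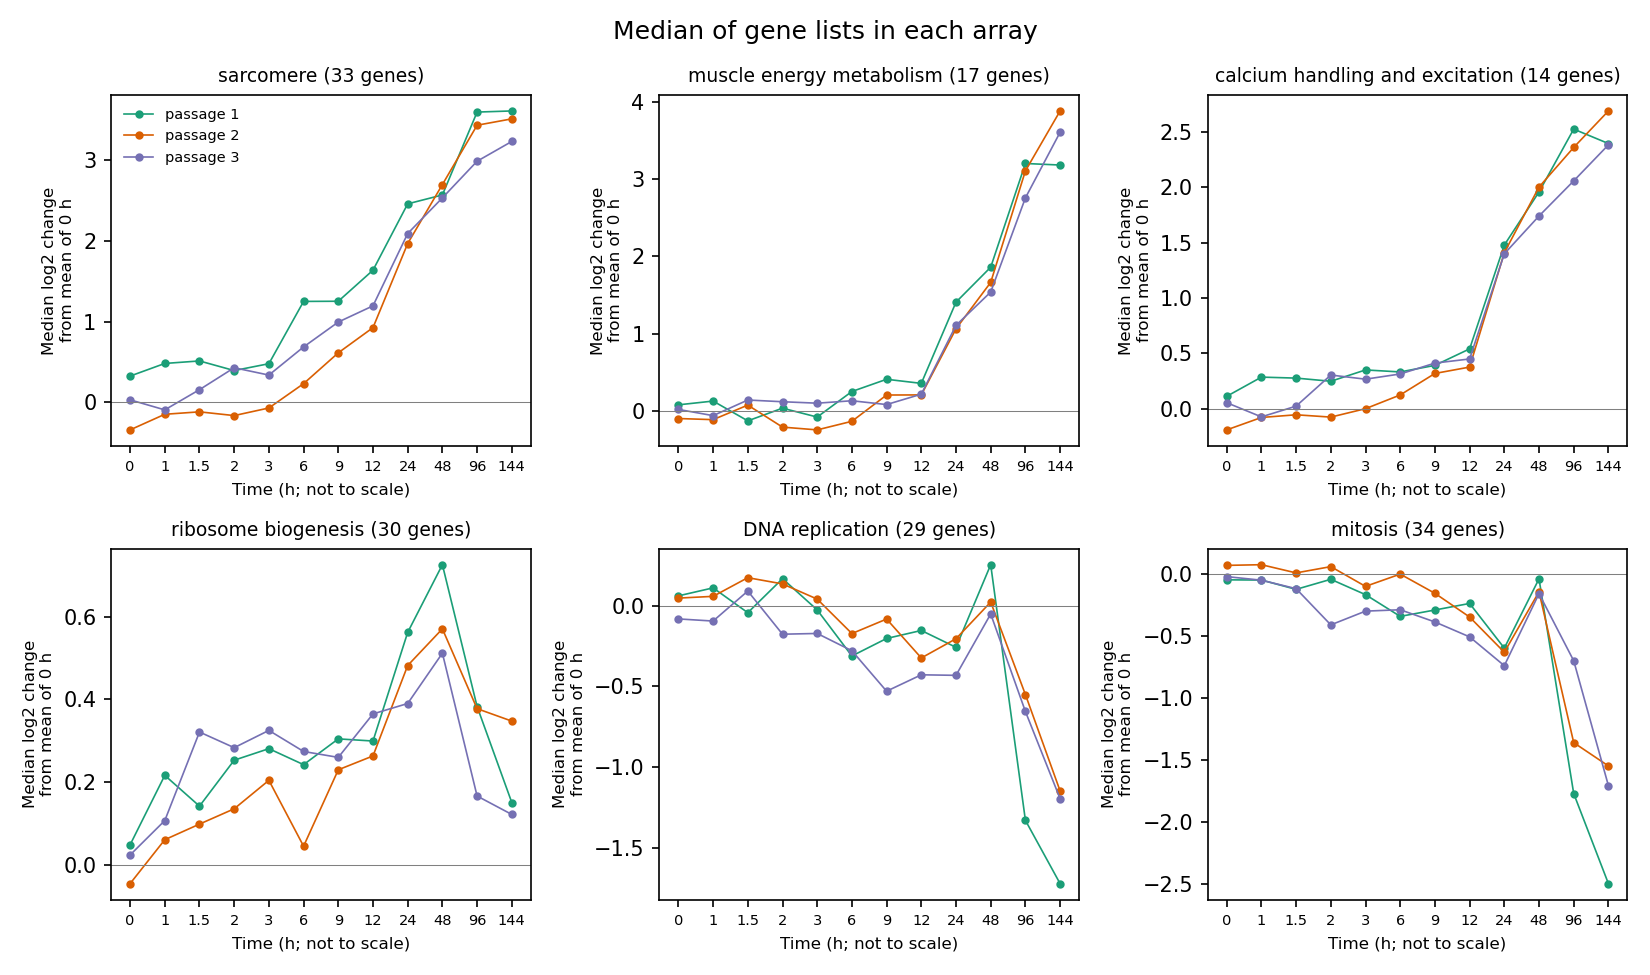
Each line joins, for 1 passage, the median over a list's genes of the log2 difference from the mean of the 0 h arrays (vertical) at the 12 times in h (horizontal, evenly spaced), for 6 lists. The median change at 144 h was 3.43 for sarcomere, 3.62 for muscle energy metabolism and −1.97 for mitosis genes.

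For the late state, 144 h was set against 0 h. Myoglobin (Mb), the oxygen store of muscle, reached 15.21 ± 0.18 from 8.33 ± 0.49 (6.89, SE 0.366, adjusted p = 2.95e-15), and the Z-disc gene Myoz2 rose by 6.85 (adjusted p = 9.27e-15). Myl2, the slow myosin light chain, was at least 77.8-fold higher, at 13.38 ± 0.41 (adjusted p = 2.59e-20). Myh8 rose by 6.55 (adjusted p = 1.27e-11) and Fxyd6, a modulator of the sodium pump, by 6.38 (SE 0.225, adjusted p = 2.88e-19). Ctrb1, a digestive proenzyme of the pancreas, rose by 6.16 to 14.02 ± 0.10 (adjusted p = 8.86e-16), read by a single probe. Lowest against 0 h were Prl2c3 and Prl2c4, at least 32.5-fold and at least 23.3-fold lower with the member uncertain, followed by the coagulation factor gene F3 (−4.08, adjusted p = 1.99e-13), the glutamate transporter Slc1a3 (−4.03), the water channel Aqp1 (−4.00) and the growth cone gene Gap43 (−3.79). Ccnd1 stood at 10.58 ± 0.43 against 13.71 ± 0.06 (−3.13, SE 0.167, adjusted p = 3.01e-15).

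The muscle lists were high at 144 h. Sarcomere genes had 30 of 33 up and Tpm1 down (−0.37), with 31 up and 1 down adjusted over the list alone and a median of 3.43 (adjusted p = 1.15e-29). All 17 energy metabolism genes rose, also adjusted over the list alone, with a median of 3.62 (adjusted p = 9.39e-25), led by Mb and Cox6a2 (6.04), a muscle subunit of cytochrome oxidase. Calcium handling had 11 of 14 up (12 adjusted over the list alone) with a median of 2.56 (adjusted p = 1.87e-13), among them Casq2 (5.09) and Hrc (4.46). Neuromuscular junction genes had 9 of 12 up (10 adjusted over the list alone) with a median of 1.06 (adjusted p = 3.51e-07), among them Chrng (3.09) and Chrnd (2.26). Adhesion and fusion genes had 9 of 18 up and 2 down (10 and 2 adjusted over the list alone) with a median of 0.32 (adjusted p = 0.000568). In that list Cav3 was at least 20.3-fold higher, Mymk rose by 4.27, and the adhesion receptor Vcam1 was lower (−1.20), with 4 other Vcam1 probes at −0.94, −0.32, −0.06 and 0.06. Within a chip the medians were 3.68, 3.65, 2.78, 0.80 and 0.25. The adjusted p with the chip as a block were 1.71e-33, 6.36e-24, 1.07e-12, 8.57e-07 and 0.00167, and these 5 calls held with an estimated correlation (adjusted p = 0.00418, 0.00227, 0.00291, 0.00314 and 0.00314).

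Proliferation genes were low at 144 h. DNA replication had 26 of 29 members down, also adjusted over the list alone, with Uhrf1 (−2.45) and Tk1 (−2.40) lowest and a median of −1.36 (adjusted p = 1.31e-15, chip block 5.87e-14, median −1.17 within a chip, and 0.11 with an estimated correlation). Mitosis had 29 of 34 down (30 adjusted over the list alone), with Nusap1 (−2.68) and Top2a (−2.53) lowest and a median of −1.97 (adjusted p = 2.91e-16, chip block 2.59e-14, median −1.74 within a chip, and 0.0557 with an estimated correlation). Id genes and BMP and TGF-beta targets had 6 of 10 down, the same adjusted over the list alone, including Id3 (−2.58), Id1 (−1.54) and Id2 (−1.46), with a median of −0.71 (adjusted p = 0.00719, chip block 0.001, median −0.90 within a chip), and held with an estimated correlation (adjusted p = 0.0194). SRF and actin genes had 9 of 18 down, the largest being Fhl2 (−1.20), and the smooth muscle protein gene Tagln up (1.38), the same adjusted over the list alone, although another Tagln probe differed by −0.13. That list had a median of −0.45 (adjusted p = 0.0153, chip block 0.00576, median −0.53 within a chip, and 0.175 with an estimated correlation), and the call was lost in 3 of 13 other settings (highest adjusted p = 0.0988). Oxidative phosphorylation had 20 of 46 up, the largest being Ndufb9 (1.17), and 2 down, among them Cox8a (−0.36), with 22 and 2 adjusted over the list alone and a median of 0.35 (adjusted p = 7.05e-05, chip block 4.17e-05, median 0.39 within a chip, and 0.11 with an estimated correlation).

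Lists that did not pass at 144 h still held changed members. Of 13 myogenic transcription factors, Mef2c (4.92), Myog (2.61), Myf6 (2.30) and Mef2a (0.55) rose, and Tcf3 (−0.79) and Eya1 (−1.03) fell. That list had 4 up and 3 down adjusted over the list alone, a median of −0.10 and a mean of 0.57 (adjusted p = 0.465). Cell cycle exit had 5 up and 2 down of 14 (adjusted p = 0.118), with Cdkn1a at least 4.39-fold higher and Cdkn1c up by 1.31. Immediate early genes had 2 up and 11 down of 30, or 2 and 12 adjusted over the list alone (adjusted p = 0.0553), among them Jun (−1.06), Egr1 (−0.76) and Myc (−0.52). Adipocyte markers had 5 of 12 down, Lpl (−3.31), Cebpa (−1.05), Pparg (−1.01), Dgat2 (−0.67) and Adipor2 (−0.30), or 1 up and 5 down adjusted over the list alone, with adjusted p = 0.118 for the list. Osteoblast markers had 1 of 8 down, Phex (dim at 144 h), and chondrocyte markers 1 of 8 down, Sox5 (−1.23), with adjusted p = 0.167 and 0.465. Neuronal markers had Eno2 up (0.76) and Gap43, Stmn2 (−2.42) and Nefm (dim at 144 h) down of 9 (adjusted p = 0.114). Reserve cell markers had 3 up and 5 down of 13 (adjusted p = 0.281), and Cd14 was the 1 leukocyte marker of 4 that passed (−0.91). Imprinted genes had Cdkn1c up and Ndn (−0.58), Mest (−0.68) and Peg3 (−1.86) down of 11 (adjusted p = 0.846). Reference genes had Tfrc up (1.66) and B2m (−0.39), Rplp0 (−0.53) and Rpl13a (−0.55) down of 12, with a median of −0.06 (adjusted p = 0.465).

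Further lists without a call at 144 h were the Notch pathway (3 up, 1 down of 13, or 4 and 1 adjusted over the list alone, adjusted p = 0.351), cholesterol synthesis (4 up, 1 down of 19, or 7 and 1 adjusted over the list alone, 0.24), ribosome biogenesis (9 up, 3 down of 30, 0.118), regulators of mitochondrial biogenesis (3 up, 1 down of 12, 0.24) and extracellular matrix (6 up, 5 down of 27, 0.804). The insulin-like growth factor and FoxO list had 2 up and 5 down of 15, with a median of 0.08 and a mean of −0.20 (adjusted p = 0.496). The clock list had 2 up and 3 down of 14 (adjusted p = 0.954), the stress-response list 4 up and 2 down of 27, or 3 and 2 adjusted over the list alone (0.264), inflammatory genes 4 up and 6 down of 16 (0.118), and hypoxia and glycolysis 7 up and 5 down of 26 (0.368). Heat shock genes had 3 of 10 up, with a median of −0.09 and a mean of 0.27 (adjusted p = 0.24). Of 14 interferon response genes 0 passed in limma and 2 were lower at an unadjusted p under 0.05 (adjusted p = 0.368 for the list). Hes1 rose by 0.55 (adjusted p = 0.0334), while Igf2 differed by 0.89 (adjusted p = 0.28, or 0.00926 with the passage as a block).

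Other probes at 144 h differed by −0.73 for Id1, −0.53 and −1.49 for Top2a, −1.74, −3.17, −2.36 and −3.12 for Ccnd1, and 0.50 and 0.21 for Mef2c. Those of Nusap1 (−0.77) and Slc1a3 (−1.29) and the first of Top2a were dim at 144 h.

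In total 4126 genes changed at 144 h (1912 higher, 2214 lower), 598 rising and 594 falling at least 2-fold, and with the chip as a block 4850 did. With cyclic loess the majority turned to 2242 higher and 1968 lower. Without passage 2 there were 2778, of which 2759 (99.3%) had the same sign on the chip of passage 2, which held both times, and without passage 3 there were 2730. Of the 45 named genes called, 37 kept their call in all 3 leave-outs of a passage, and Cox8a, Hes1, Mef2a and Tpm1 lost it under at least 1 other processing, Tpm1 with the chip as a block (adjusted p = 0.0693) among them.

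A direct comparison of 24 h with 3 h asked what changed between the early and the middle phase. Actn2 rose by 4.86 (SE 0.433, adjusted p = 1.57e-09), Myh8 by 4.75 (adjusted p = 5.29e-08), and Ankrd2, dim at 3 h, was higher (adjusted p = 6.29e-12). Gpr176, higher at 3 h, was lower by 24 h (−2.44, SE 0.216, adjusted p = 1.41e-09), as were Phex (−2.39, adjusted p = 3.66e-07) and, with the member uncertain, Prl2c3 (−2.34, adjusted p = 4.87e-06). Myog rose by 2.22, Id1 by 0.67 (adjusted p = 0.0134, another probe 0.20), Hes1, a Notch target, by 0.83 (adjusted p = 0.00395) and Pax7, a satellite cell factor, by 0.65 (adjusted p = 0.0043). Igf2 and Myf5 passed with the passage as a block alone (adjusted p = 0.121 and 0.000311 for Igf2, and 0.217 and 0.0221 for Myf5). The list test here was added after the values were seen, and 16 of 32 lists passed, 12 of them up and 4 down. SRF and actin genes had 5 of 18 down, Pdlim5 (−1.34), Actg2 (−0.76), Vcl (−0.68), Tpm4 (−0.64) and Fhl2 (−0.59), with 6 adjusted over the list alone and a median of −0.38 (adjusted p = 4.16e-05, chip block 9.59e-05, median −0.41 within a chip). It held with an estimated correlation (adjusted p = 0.024), though not when the passage block was added (0.0618). Notch pathway genes had 4 of 13 up, Heyl (1.48), Hes1, Nrarp (0.72) and Notch3 (0.67), with 5 adjusted over the list alone and a median of 0.22 (adjusted p = 0.0164, chip block 0.0108, median 0.33 within a chip, and 0.0383 with an estimated correlation).

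The other 14 lists that passed for 24 h against 3 h included the 5 muscle lists, which held with an estimated correlation (adjusted p = 0.00911, 0.00252, 0.00252, 0.024 and 0.00461). In that order these were sarcomere (24 of 33 up, 1 down, and 25 and 1 adjusted over the list alone, median 1.89), energy metabolism (13 of 17 up, 14 adjusted over the list alone, median 1.39), calcium handling (9 of 14 up, 11 adjusted over the list alone, median 1.32), neuromuscular junction (4 of 12 up, 5 adjusted over the list alone, median 0.29) and adhesion and fusion (6 of 18 up, 1 down, and 7 and 2 adjusted over the list alone, median 0.16, mean 0.56). Their adjusted p with the chip as a block were 1.79e-34, 3.78e-21, 3.84e-13, 0.000561 and 0.000517, and their medians within a chip 1.95, 1.16, 1.18, 0.31 and 0.10.

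The remaining 9 list calls for 24 h against 3 h were lost with an estimated correlation, whose adjusted p is given last for each. Cholesterol synthesis had 5 of 19 up (8 adjusted over the list alone) and a median of 0.43 (adjusted p = 0.000653, chip block 0.00196, median 0.14 within a chip, and 0.283). Ribosome biogenesis had 7 of 30 up (8 adjusted over the list alone) and a median of 0.20 (adjusted p = 0.0089, chip block 0.0458, 0.25 within a chip, and 0.283). Oxidative phosphorylation had 5 of 46 up and a median of 0.14 (adjusted p = 0.0107, chip block 0.0402, 0.12 within a chip, and 0.281), and the stress-response list 5 of 27 up (7 adjusted over the list alone) and 0.10 (adjusted p = 0.0285, chip block 0.0321, 0.15 within a chip, and 0.272). Mitosis had 2 of 34 down (0 adjusted over the list alone) and a median of −0.48 (adjusted p = 9.07e-06, chip block 0.000517, −0.53 within a chip, and 0.281). Extracellular matrix had 1 up and 5 down of 27 (1 and 6 adjusted over the list alone) and a median of −0.22 (adjusted p = 0.00704, chip block 0.0321, −0.20 within a chip, and 0.218). DNA replication had 1 of 29 up and a median of −0.29 (adjusted p = 0.00395, or 0.0837 with the chip as a block, −0.27 within a chip, and 0.496). Heat shock (4 of 10 up, median 0.13, adjusted p = 0.0461, chip block 0.0434, 0.11 within a chip, and 0.0978) and imprinted genes (2 of 11 up, median 0.14, adjusted p = 0.0461, chip block 0.0458, 0.09 within a chip, and 0.0978) also lost their calls with the passage as a block (0.0512 and 0.0666). Neuronal markers passed with the passage or the chip as a block (adjusted p = 0.0586, or 0.0241 and 0.0338), but not with an estimated correlation (0.319, or 0.0953 when the passage block was added).

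Between these times limma called 1558 genes (964 higher, 594 lower), against 2542 with the passage and 2166 with the chip as a block. Without passage 2 there were 763, all with the same sign on the chip of passage 2 that held both times. Without passage 3 there were 747, and scaling to the median gave 853 higher and 262 lower. Of the 17 named genes called, 11 kept their call in all 3 leave-outs of a passage, and Acta1, Ccnd1, Hes1, Id1, Myog and Pax7 did not. Ccnd1 also lost its call with the chip as a block (adjusted p = 0.0771), scaling to the median (0.249) and no filter (0.0543).

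Maturation from 24 to 144 h was the last question. Myl2 rose by 5.13 (SE 0.203, adjusted p = 2.75e-17), the tetraspanin gene Tspan8 by 4.77 (SE 0.355, adjusted p = 2.32e-11) and Fxyd6 by 4.04 (adjusted p = 5.76e-14). Ptn (pleiotrophin), a secreted growth factor, was lower (−3.16, SE 0.165, adjusted p = 1.56e-14). Prl2c3 and Prl2c4 were at least 7.13-fold and at least 4.97-fold lower, with the member uncertain. Mef2c rose by 3.50 and Myf6 by 2.54. Other Mef2c probes differed by −0.04 and, dim at 24 h, by 0.56 (adjusted p = 0.0103). Cdkn1c (−2.42), Ccnd1 (−2.33, with −1.07, −2.30, −1.50 and −2.37 at 4 other probes), Id3 (−0.99) and Jun (−0.77) were lower, while Myog (−0.31), Mymk (0.28) and Ckm (0.54) did not pass. Myc (−0.47, adjusted p = 0.0333) lost its call with the chip as a block (adjusted p = 0.064), in the authors' normalized table (0.0914), in the series matrix (0.0916), with scaling to the median (0.123) and with cyclic loess (0.0798), and Egr1 passed with the passage as a block alone (adjusted p = 0.0933 and 0.0133).

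Energy metabolism genes had 15 of 17 up from 24 to 144 h (16 adjusted over the list alone), among them Mb (3.35) and Cox7a1 (3.15), with a median of 1.80 (adjusted p = 5.77e-22, chip block 3.52e-22, median 1.50 within a chip), and held with an estimated correlation (adjusted p = 0.00431). The other 10 list calls here were lost with an estimated correlation, whose adjusted p is given last for each. Sarcomere genes had 20 of 33 up (22 adjusted over the list alone) with a median of 1.24 (adjusted p = 3.26e-14, chip block 1.69e-15, median 1.13 within a chip, and 0.111). Calcium handling had 6 of 14 up (8 adjusted over the list alone), among them Casq1 (3.16), with a median of 0.68 (adjusted p = 1.07e-05, chip block 2.81e-05, median 0.69 within a chip, and 0.11). Neuromuscular junction had Chrne (2.13), Chrnd (0.66) and Colq (dim at 24 h) up of 12 (4 adjusted over the list alone) with a median of 0.26 (adjusted p = 0.00527, chip block 0.00601, median 0.30 within a chip, and 0.118). DNA replication had 24 of 29 down (25 adjusted over the list alone) with a median of −1.03 (adjusted p = 4.88e-17, chip block 3.04e-17, median −1.49 within a chip, and 0.118). Mitosis had 21 of 34 down (24 adjusted over the list alone) with a median of −1.19 (adjusted p = 9.72e-13, chip block 5.5e-12, median −1.91 within a chip, and 0.118).

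Ribosome biogenesis had 6 of 30 down (7 adjusted over the list alone), among them Fbl (−0.93) and Gar1 (−0.74), with a median of −0.30 (adjusted p = 0.00146, chip block 0.0012, median −0.35 within a chip, and 0.285 with an estimated correlation). Imprinted genes had Cdkn1c, Mest (−1.83) and Peg3 (−1.05) down of 11, the same adjusted over the list alone, with a median of −0.24 (adjusted p = 0.0179, chip block 0.00767, median −0.38 within a chip, and 0.11 with an estimated correlation). Reserve cell markers had 6 of 13 down (8 adjusted over the list alone), among them Vcam1 (−1.02) and Pax7 (−0.47), and Tenm4 up (0.83), with a median of −0.38 (adjusted p = 0.0286, chip block 0.0253, median −0.38 within a chip, and 0.21 with an estimated correlation). Hypoxia and glycolysis genes had 6 of 26 up and Bnip3l down (−0.39), the same adjusted over the list alone, with a median of 0.18 (adjusted p = 0.012, chip block 0.0381, median 0.03 within a chip, and 0.349 with an estimated correlation). Oxidative phosphorylation had Ndufb7 (0.55), Ndufs3 (0.48), Cox5a (0.39), Ndufa1 (0.28) and Ndufb8 (0.27) up of 46 and Uqcrq (−0.55) and Cox8a (−0.39) down, the same counts adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0407, chip block 0.0238, median 0.04 within a chip, and 0.461 with an estimated correlation). Extracellular matrix genes passed with the passage as a block (adjusted p = 0.0859 and 0.0411), but not with an estimated correlation (0.461, or 0.37 when the passage block was added). Over 13 other settings, calls were lost in 4 for oxidative phosphorylation (highest adjusted p = 0.132), in 2 for reserve cell markers (0.132) and in 1 for hypoxia and glycolysis (0.1), and that of Pax7 with scaling to the median (0.0798) and cyclic loess (0.0708).

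Across this interval 2478 genes changed (1094 higher, 1384 lower), and with the chip as a block 3104 did. The majority turned to higher genes with scaling to the median (952 higher, 839 lower) and cyclic loess (1377 and 1195), and without passage 1 the split was 1233 and 1232. Of these 2465, 2296 (93.1%) had the same sign on the chip of passage 1 that held both times. There were 1298 without passage 2 and 1339 without passage 3. Of the 15 named genes called, 12 kept their call in all 3 leave-outs of a passage, and Id1, Myc and Pax7 did not.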

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

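The tests of other splits of the arrays, with or without the replicate number kept, of a chip for passage 1, of array brightness, of the other Trib3 probes, of the wider stress-response list and of the pancreatic markers were chosen only after the result was seen, as was the list test at 24 h against 3 h.

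A set of results stood out because the effect differed between times when the difference itself was tested. The SRF and actin list had a median of 0.17 at 3 h and −0.24 at 24 h against 0 h, and 24 h against 3 h gave −0.38 (camera adjusted p = 4.16e-05, or 0.0618 with the passage block and an estimated correlation). With scaling to the median the values at 3 h and for 24 h against 3 h were 0.05 and −0.21. Gpr176 rose by 1.56 at 3 h, and 24 h against 3 h gave −2.44 (limma adjusted p = 1.41e-09). Mest rose by 1.15 at 24 h, and 144 h against 24 h gave −1.83. Outside the named genes, 1427 of 9644 unnamed probes changed at 144 h (614 higher, 813 lower). Groups of 3 are too small for the test of single arrays far from the others, which was not applied.

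Sarcomere genes differed between the passages over 0 to 3 h. The 33 genes lay a median of 0.68 higher in passage 1 than in passage 2, while 10000 lists matched on mean level gave −0.19 to 0.09, which argues against array brightness and background as the whole source. Passage 3 lay above passage 2 by 0.51 on the chips that held 2 and 3 h and by 0.17 on those that held 0 to 1.5 h. Both lay outside all matched lists (−0.15 to 0.14, and −0.14 to 0.12). Matched lists were drawn from unrelated genes, so their ranges allow for no correlation between members, estimated at 0.334 for the sarcomere list. The 0.17 lay close to its range, so a single chip that stands apart is not decided for these passages. For passage 1 against passage 2 such a chip cannot be told apart, because 1 chip held all passage 1 arrays of 0 to 3 h. The median levels of the 33 genes were 8.83, 8.36 and 8.88 in passages 1, 2 and 3, so passage 2 was the lowest. A candidate explanation is that cultures of passage 1 were further along in differentiation than those of passage 2. Of the 846 genes that fell at 24 h, 74.9% were lower in passage 1 than in passage 2, against 57.8 to 70.6% in matched sets. Of 990 risen genes 50.4% were higher, against 30.8 to 42.0%. These genes were called from the same arrays, and the 0 h arrays entered both the call and the passage difference. The matched sets held uncalled genes, so their ranges are too narrow for genes that vary together, and the explanation stays a candidate. Passage 3 was not put to this test. A culture or hybridisation batch of a whole passage cannot be told apart from earlier differentiation, because each chip held 1 passage.

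Trib3 and Chac1 fell by 3 h. The other Trib3 probes stood little above the filter level at 0 h (7.23 for the dimmer one) and, dim, at 6.79 and 6.64 at 3 h, which leaves no room for a fall of that size. Their changes of −0.45 (adjusted p = 0.812) and −0.86 (adjusted p = 0.353) therefore decide nothing, and a fault of the probe used and a true fall cannot be told apart for Trib3. Whether a lower integrated stress response is part of it stays open. The 27 other members had a median of −0.10, against −0.08 at the 2.5th percentile of matched lists (lowest −0.18, median −0.00). Matched lists were drawn from unrelated genes, so their range allows for no correlation between members. The shift is small, and 21 of the 27 lay below 0, 1 rose (Stc2) and 1 fell (Cebpb). Of the 27, 15 are also in the fixed stress-response list, which did not pass (camera adjusted p = 0.259, or 0.613 with an estimated correlation). The change of medium itself stays open, because 0 groups of cultures received fresh growth medium only.

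Ctrb1 rose from 7.86 at 0 h to 14.02 at 144 h. RNA from pancreas is argued against, since the 21 other pancreatic markers with a named probe, 15 of them above the filter level, had a median change of 0.0652 (SD 0.477), and 1 of them rose by at least 1 log2 unit (Rnase1, dim at 0 h). The criterion of this test was rewritten after the values were seen, because Cela1, the brightest other marker (11.01 at 144 h), was already bright at 0 h and had left the first version undecided. Another transcript read by the Ctrb1 probe cannot be told apart, since the array has 0 other Ctrb1 probes. A biological source was not tested.

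A count of genes differing among the 12 times as high as the real one was not reached by random draws, which do not test any single gene. Of 100 draws of 12 groups of 3 arrays, the real grouping included, 1 gave as many genes, with 5495 in the real grouping and 1643 in the highest other. These draws ignored the replicate number, so most of their groups did not hold 1 array of each. With the times exchanged only among arrays of the same number, 1 of 100 draws, the real one, gave as many, and the highest other gave 15. Each comparison of 2 times has 10 splits of its 6 arrays, too few for a share under 0.05. The real counts were 45, 95, 153, 135, 207, 347, 476, 1860, 3743, 4280 and 4126 from 1 to 144 h against 0 h, 1558 for 24 h against 3 h and 2478 for 144 h against 24 h. The highest other split gave 1 gene at 1.5 h and for 144 h against 24 h, and 0 in limma elsewhere. Over the 117 other splits of the 13 comparisons, 168 to 2091 genes (median 583) had an unadjusted p under 0.05. Among splits that parted all 3 pairs of the same number, the highest other was 0. Every other split put arrays of both times into each group, which shrinks a real change and widens the spread. Low counts there were therefore likely in any case and do not measure the rate of false calls.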

How the results depend on the processing

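All values here were planned except those chosen after the data were seen. These were the values with a replicate block and an estimated correlation together and those for the times of highest and lowest means. The list values for 24 h against 3 h, which gave 16 of the 60 list calls, were also unplanned. Of 240 counts under other settings, 188 lay within 1.5 times of the value reported and 52 did not. In this and the next tallies the series matrix counts apart from the authors' normalized table, although its values are the same. Of 135 counts with arrays left out, 75 did and 60 did not. Named genes gave 2996 values under other processing, of which 2785 kept their direction and side of the threshold, 134 lost a call, 37 gained one, 0 reversed and 40 changed sign without a call in either. The naming rule asked for the same sign in every passage for the largest rises and falls, which works against a reversal there. Of 90 values of other probes 49 kept both, 28 lost a call, 2 gained one, 7 reversed and 4 changed sign without a call in either. Of the 60 list calls, 0 medians turned sign under another scaling or table, but 27 moved by over 1.5 times. Dim genes limit the reach, since the offset shrinks their changes, and unless said otherwise the cause of a difference was not tested.

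With the replicate number as a block the counts at 1, 1.5, 2, 3, 6, 9, 12 and 24 h against 0 h were 76, 255, 401, 524, 673, 828, 1060 and 2890, and 24 h against 3 h gave 2542. With the chip as a fixed block the counts at 1 to 12 h were 97, 283, 372, 582, 725, 858 and 1029, and as a random block 88, 266, 364, 455, 585, 746 and 909. Scaling to the median gave 28, 33, 45, 65, 63, 205 and 308 at these times. With only the arrays of both times the model had fewer samples and called 7, 0, 13, 8 and 29 genes at 1, 1.5, 2, 3 and 6 h, 51 at 9 h, and 1536 for 144 h against 24 h. The 0 in limma stood beside 792 genes with an unadjusted p under 0.05, where a share of 0.05 of 13251 genes is expected without any change. Every probe on its own, a larger set of features, gave 9395 in the F-test, 6160, 7345 and 6792 at 48, 96 and 144 h, and 3782 for 144 h against 24 h. In the authors' normalized table and in the series matrix 1156 genes spanned at least 1 log2 unit, where the floor of that table narrows the scale.

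List medians that moved by over 1.5 times are given with the value furthest from the one reported. In the authors' normalized table, whose scale is narrower, they were at 3 h 0.16 for sarcomere and −0.04 for Id genes, at 24 h 0.81 for energy metabolism, 0.09 for adhesion and fusion, −0.05 for immediate early genes, −0.39 for Id genes, −0.12 for neuronal markers and 0.01 for imprinted genes, and at 144 h 0.61 for neuromuscular junction and −0.44 for Id genes. For 144 h against 24 h they were −0.18 for reserve cell markers and −0.07 for imprinted genes, and for 24 h against 3 h 1.25 for sarcomere, 0.13 for Notch, 0.25 for cholesterol synthesis, 0.13 for ribosome biogenesis, 0.04 for heat shock and 0.01 for imprinted genes. With scaling to the median they were at 3 h 0.05 for SRF and actin, 0.17 for ribosome biogenesis and −0.26 for clock genes, and at 24 h −0.14 for cell cycle exit and 0.11 for heat shock. For 24 h against 3 h they were −0.21 for SRF and actin, 0.31 for oxidative phosphorylation, −0.13 for extracellular matrix and 0.23 for the stress-response list.

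With an estimated correlation 0 lists passed at 3 h (camera, 5 at an unadjusted p under 0.05), 7 at 24 h, 6 at 144 h and 1 for 144 h against 24 h. With the replicate block and an estimated correlation 0 passed at 3 h (3 at an unadjusted p under 0.05), 8 at 24 h, 6 at 144 h and 1 for 144 h against 24 h.

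Other probes of called genes went the other way for Mcm4 (0.17), 1 of 2 for Mef2c (−0.0569), 1 of 3 for Tyms (0.0219) and Uqcrq (−0.0222) at 24 h, for Tagln (−0.13) and 1 of 4 for Vcam1 (0.0639) at 144 h, and for Mef2c (−0.0440) at 144 h against 24 h. The probes of Mcm4, Mef2c and Uqcrq at 24 h and of Tagln at 144 h were dim in both groups.

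Leaving out a passage gave 3175 to 5016 genes in the F-test and 1829 to 2273 that spanned at least 1 log2 unit. For the comparisons of 2 times, the gene counts are given without a passage or without a single array. Against 0 h the counts ran from 4 to 39 at 1 h, 0 to 93 at 1.5 h, 0 to 131 at 2 h, 1 to 121 at 3 h, 16 to 208 at 6 h, 73 to 300 at 9 h, 115 to 410 at 12 h, 780 to 1895 at 24 h, 2231 to 3641 at 48 h, 2702 to 4098 at 96 h and 2730 to 4314 at 144 h. The counts of 0, both without replicate 3, stood beside 511 and 637 genes with an unadjusted p under 0.05 in limma. Neither number exceeded the share of 0.05 of 13251 genes expected without any change. For 24 h against 3 h the counts ran from 747 to 1369 and for 144 h against 24 h from 1298 to 2465. Without a passage, lists that passed numbered 2 to 10 at 3 h, 14 to 19 at 24 h, 9 to 11 at 144 h and 9 to 11 for 144 h against 24 h. The lowest counts of the F-test and of the 13 comparisons came without passage 2 or 3.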

Other observations

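The genes and lists in this part were chosen after their values were seen, from the fixed tests against 0 h at the other times. At 1 h Edn1 (endothelin 1) rose by 2.29 (SE 0.267, limma adjusted p = 2.76e-05), the matricellular genes Ccn1 and Ccn2 by 2.28 (adjusted p = 0.0162) and 1.78 (adjusted p = 0.00224), Ankrd1 by 1.48 (adjusted p = 0.000861) and Rgs16, a regulator of G protein signalling, by 1.40 (adjusted p = 0.00027). Lower at 1 h were Socs3, a suppressor of cytokine signalling (−1.22, adjusted p = 0.000183), the phosphodiesterase gene Pde4b (−0.97) and Rgs2 (−0.94). Of 30 immediate early genes 13 rose at 1 h, with a list median of 0.61, and 4 rose at 1.5 h, with a median of 0.14. These counts did not hold in every leave-out of a passage. At 1 h limma called 5 genes of any kind without passage 2 and 4 without passage 3, and at 1.5 h 0 without passage 3. The changes at 1 and 1.5 h cannot be told apart from an effect of the change of medium itself, because no cultures received fresh growth medium only. At 2 h the transcription factor gene Klf5 rose by 1.11 (adjusted p = 0.000272) and the kinase gene Nuak1 by 1.05 (adjusted p = 2.34e-05), and the chemokine genes Cxcl1 (−1.03) and Ccl7 (−1.07) were lower. At 6 h the muscle genes Klhl41 (1.71, adjusted p = 0.00628), Smyd1 (1.58, adjusted p = 0.0199) and Klhl40 (1.50, adjusted p = 3.44e-05) and the transferrin receptor gene Tfrc (1.53, adjusted p = 0.00384) rose. By 9 h 17 of 33 sarcomere genes were higher, among them Mybph (2.78) and Actc1 (2.16), and the list median was 1.08.

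At 48 h, 12 of 19 cholesterol synthesis genes rose, with a median of 0.69, and 19 of 30 ribosome biogenesis genes rose, with a median of 0.61. DNA replication genes had a median of 0.05 at 48 h (1 up, 1 down of 29), against −0.33 at 24 h and −1.36 at 144 h, and mitosis genes −0.13 (2 of 34 down), against −0.70 and −1.97. The differences of 48 h from 24 and 144 h were not tested. Clock genes had 3 up and 6 down of 14 at 48 h. The lipoprotein lipase gene Lpl was lower at 48 h (−3.63, adjusted p = 2.43e-06) and 96 h (−3.95, adjusted p = 4.29e-07), and the surface protein gene Ly6d, dim at 96 h, was lower there (adjusted p = 8.02e-09). The Trib3 probe used, whose fault stays open, and Chac1, both low at 3 h, rose by 1.68 (adjusted p = 0.0026) and 1.41 (adjusted p = 0.000607) at 96 h.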
